A study of Mus musculus with 6 samples.

How the data were processed

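Single-cell RNA sequencing was measured in 6 libraries of mouse fibro-adipogenic progenitors (FAPs), the PDGFRα-positive fibroblast-like cells that lie between muscle fibres. Cells were sorted on a PDGFRα-GFP reporter from diaphragm, heart and tibialis anterior of mice labelled PRURDBA and PRURD2, per the labels' protocols. For each tissue the cells of 3 mice of a genotype were pooled into 1 lane, so that each combination of tissue and genotype is 1 library. The series title names the D2-mdx mouse, a model of Duchenne muscular dystrophy with a mutation in Dmd, but the labels do not state which genotype carries the mutation, so the genotype labels are used as names only.

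The deposited values are raw UMI counts per gene and cell barcode, with no normalization. The matrices were written by Cell Ranger 5.0.1 per the file headers, while the submitters' processing notes name Cell Ranger 9.0.1 and the build mm10. The design text and the labels' extraction protocol also name different generations of the 10x Genomics kit and different collagenase doses. These conflicts were left open, since none of them could be settled from the values. The design text describes doublet removal with DoubletFinder, but whether the matrices hold barcodes from before or after that step is not stated. The study's pseudobulk tests, pseudotime and cell communication methods, named in the same text, were not used here. The GFP reporter is not among the 32285 genes of the files.

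Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with Scrublet (in scanpy 1.11.5), and the top-ranked 0.8% per 1000 barcodes of each library were removed. Scrublet's own threshold would have marked from 0 to 0.0789% of barcodes in 5 libraries and 2.52% in PRURD2 tibialis anterior. The libraries of each tissue were clustered together in Seurat 5.3.0 with canonical correlation integration, 2000 variable genes, 30 dimensions and resolution 0.4. Cluster borders depended slightly on the rounding of the linear algebra library, which was therefore fixed to its Haswell routines. Clusters were named from 13 marker lists of cell types and 10 of fibroblast subsets. A cell type or subset name needed at least 3 of its markers among the 10 leading genes of a cluster. A cluster counted as fibroblast-like when at least 3 fibroblast markers reached 100 CPM, no other type led it, and its depth was not far below the library's. This naming rule was settled after the clusters had been seen. Names end in "-like" because they rest on markers alone.

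Counts of fibroblast-like cells were summed per library and expressed as CPM, the count of a gene relative to all counts of the library on the usual scale. Genotypes were compared within each tissue as the ratio of CPM in PRURD2 over PRURDBA, with an exact conditional binomial 95% interval of the ratio. With 1 library per group there are no replicates and no test of the genotype was made. All intervals cover counting error only, not differences between mice or lanes. A gene was counted as higher or lower by size alone, when it differed at least 2-fold and reached 20 CPM in the higher library. Members of gene lists were counted by the same size rule. Shares of cells are given with exact Clopper-Pearson 95% intervals. A UMI count of 0 was read as at most 3 counts. Over 23 gene lists, the median log2 ratio of members with at least 5 CPM was set against 10000 random lists of the same size matched on expression in 20 bins. A list is described as standing apart where its median lay outside the middle 95% of its random lists, which describes these libraries and is not a test. The same ratios were taken between tissues within each genotype.

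The groups, comparisons, gene lists, markers, filters and alternatives were chosen before the data were examined. The named genes were the 10 highest and 10 lowest ratios among genes past the size rule in each tissue and tissue contrast, and up to 4 members of each list with the largest log2 ratios, of which 2 genes of the tissue contrasts are not reported here. Dmd, Pdgfra, Col1a1, Col3a1, Fn1, Postn, Acta2 and Tgfb1 were always given. Gene models without a name, mitochondrial, ribosomal, haemoglobin and sex-linked marker genes were left out of the rankings but stayed in the counts. Markers of other cell types and genes over 5 times higher in another cell class of the tissue were left out of both. Coordinates are those of GENCODE vM21 on mm10.

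Alternatives were TMM scaling (edgeR 4.0.16, R 4.3.3), minima of 5 and 50 CPM, doublets kept, a stricter cell filter of 1000 genes and 5% mitochondrial UMIs, and all filtered cells summed. Further alternatives weighted each cell equally, thinned every cell to 2000 UMIs, left no gene out, or gave each cluster the same weight in both genotypes ("cluster-standardised"). Clustering was repeated without integration and at resolution 0.8. The comparison code was tested on simulated Poisson counts of the 32285 genes with 100 genes raised or lowered 3-fold and 100 by less than the size rule. These counts held counting error only, with no variation between mice or lanes, so that they check the code alone. All 100 genes with a 3-fold difference were recovered in each tissue, and none of the unchanged genes was called. At this depth such an outcome was close to certain. It does not show how often mice or lanes would differ 2-fold. The intervals covered the true ratio for 95.02% of genes in the diaphragm, 95.5% in heart and 95.05% in tibialis anterior simulations. Of 200 random lists, 12, 5 and 14 fell outside the middle 95%. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

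Depth set the precision. The fibroblast-like sums held from 68933008 UMIs (PRURD2 diaphragm) to 107952811 UMIs (PRURDBA tibialis anterior). A floor of 3 counts corresponded to 0.0278 to 0.0435 CPM.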

Results

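The data are 6 single-cell libraries, 1 for each of 3 tissues in each of 2 genotypes, PRURDBA and PRURD2. The diaphragm libraries held 10526 barcodes and 96864112 UMIs in PRURDBA and 8204 barcodes and 78376765 UMIs in PRURD2. The heart libraries held 7288 barcodes with 90855696 UMIs and 7417 barcodes with 86092524 UMIs, in the same order. The tibialis anterior libraries held 19193 barcodes with 134591853 UMIs and 10589 barcodes with 116569474 UMIs. After filtering, 9521 and 7515 diaphragm cells, 6681 and 5962 heart cells, and 15587 and 9430 tibialis anterior cells were kept for PRURDBA and PRURD2. Median depth per kept cell was 8442 and 9134 UMIs in diaphragm, 12118 and 12939 in heart, and 6460 and 10327.5 in tibialis anterior, so that the genotypes differed most in depth in tibialis anterior.

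Fibroblast-like cells, the population that the PDGFRα-GFP sort targeted, made up most of each library. Their share in PRURDBA and PRURD2 was 90.5% (95% interval 89.9 to 91.0) and 96.0% (95.5 to 96.4) in diaphragm and 94.9% (94.4 to 95.4) and 92.6% (91.9 to 93.2) in heart. In tibialis anterior it was 84.7% (84.1 to 85.2) and 98.8% (98.5 to 99.0). The clusters left out of the fibroblast-like sums were small, except for a cluster of low depth that held 15.2% of PRURDBA and 0.880% of PRURD2 tibialis anterior cells. Low-depth clusters held 2.29% and 1.30% of diaphragm cells and 2.59% and 5.07% of heart cells. Endothelial-like cells held 2.04% and 2.08% of heart cells, and macrophage-like cells 0.420% and 0.160% of diaphragm cells.

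Dmd (ENSMUSG00000045103, chromosome X from 82948870 to 85206141), the dystrophin gene mutated in mdx mice, was detected in both genotypes. It was 1.45-fold higher in PRURD2 in diaphragm (16.2 CPM in PRURDBA, 23.5 CPM in PRURD2; 95% interval 1.34 to 1.56). The ratio was 1.11 in heart (24.9 and 27.6 CPM) and 1.21 in tibialis anterior (13.02 and 15.8 CPM). Tags from the 3' end of the transcript do not read the mutation, so these counts do not check the genotype labels. Pdgfra, the receptor gene behind the sort reporter, was at 239 and 249 CPM in diaphragm, 220 and 255 CPM in heart, and 235 and 198 CPM in tibialis anterior. With every cell thinned to 2000 UMIs, a Pdgfra UMI was seen in 36.8% and 37.9% of diaphragm, 33.6% and 38.1% of heart, and 36.1% and 31.7% of tibialis anterior fibroblast-like cells. The same share among endothelial-like and macrophage-like cells, which should lack Pdgfra, was 8.75% and 9.02% in heart (14 of 160 and 12 of 133 cells). In diaphragm it was 0 of 44 cells in PRURDBA and 0 of 28 cells in PRURD2, which allows up to 8.04% and 12.3%. In tibialis anterior it was 4.76% (1 of 21) in PRURDBA and 0 of 27 in PRURD2, which allows up to 12.8%. Before thinning, the median depth of the fibroblast-like and of the other cells was 12310 and 8120.5 UMIs in PRURDBA heart and 13297 and 7306 UMIs in PRURD2 heart.

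The first comparison asked how diaphragm FAPs of the genotypes differ, the diaphragm being the muscle in which fibrosis is most marked in mdx mice. Some genes of activated fibroblasts and of the matrix were lower in PRURD2, among them Timp1, an inhibitor of matrix metalloproteinases, which was 6.76-fold lower (325 CPM in PRURDBA, 48.0 CPM in PRURD2; 95% interval 6.52 to 7.01). Postn, the matricellular protein periostin that marks activated fibroblasts, was 4.85-fold lower (366 and 75.5 CPM; 4.71 to 5.00), and Fbln7, a fibulin of the extracellular matrix, 7.12-fold lower (122 and 17.2 CPM; 6.70 to 7.57). With clusters weighed alike, the log2 ratio moved from -2.76 to -2.20 for Timp1, -2.28 to -2.06 for Postn and -2.83 to -2.34 for Fbln7. A cluster led by Timp1 and named inflammatory-like held 9974 Timp1 UMIs in 211 PRURDBA cells and 1112 in 57 PRURD2 cells. Higher in PRURD2 were Pgf, which encodes placental growth factor, by 6.10-fold (14.5 and 88.7 CPM; 5.73 to 6.51), and Ccl11, which encodes the eosinophil attractant eotaxin, by 3.55-fold (249 and 882 CPM). Of 5726 genes compared, 71 were at least 2-fold higher and 75 at least 2-fold lower in PRURD2, while the median log2 ratio of all genes was 0.07.

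Among the other lowest genes of diaphragm were Pax1, a developmental transcription factor, at 40.9 and 4.95 CPM (8.27-fold lower) and its overlapping antisense neighbour AI646519 at 29.7 and 3.42 CPM (8.66-fold lower). Hp, which encodes the haemoglobin-binding haptoglobin, was 7.95-fold lower, the chemokine gene Cxcl5 6.17-fold, C1qtnf3 6.10-fold, tenascin gene Tnc 4.99-fold and the cartilage matrix gene Comp 4.80-fold. Among the highest were Col4a4, a basement membrane collagen chain, 5.72-fold (4.30 and 24.6 CPM), the receptor partner Ramp1 4.47-fold and Aldh1a2, which makes retinoic acid, 3.93-fold. Ces1d was 3.55-fold, Pcsk6 3.48-fold, Ret, the receptor kinase for GDNF family ligands, 3.31-fold, Stmn4 3.27-fold and Thsd7a 3.23-fold higher in PRURD2.

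The matricellular and activated fibroblast list had the lowest median log2 ratio of all lists in diaphragm, -1.12, with 8 of 23 measured members lower and 2 higher by the size rule (at least 2-fold apart and at least 20 CPM in the higher library), which all counts of list members follow. Besides Postn, Tnc and Comp, the lower members included Thbs4 (707 and 208 CPM) and Runx1 (217 and 65.5 CPM), while the thrombospondin gene Thbs1 (254 and 562 CPM) and Ccn3 (94.2 and 203 CPM) were higher. The skeletogenic and tendon list was also lower (median -1.005, 4 of 13 lower by the size rule), with Fmod, a small proteoglycan of tendon, at 83.4 and 23.3 CPM. Its member Bmp2 was 2.57-fold higher in PRURD2. Collagens were lower as a list (median -0.32, 2 of 17 lower by the size rule). The main fibril collagens differed less than 2-fold, with Col1a1 at 1122 and 688 CPM and Col3a1 at 3030 and 2426 CPM, and Col6a5 was 2.85-fold lower. The basement membrane list went the other way, with all 16 measured members above 0 and a median of 0.60. Of these, Col4a4 alone passed the size rule, and Lamb1, a laminin chain, was at 135 and 227 CPM. The contractile list had a median of -0.30, with the actin-bundling genes Actn1 (2.61-fold) and Palld (2.57-fold) lower. Acta2, the smooth muscle actin of myofibroblasts, stood at 8.46 and 3.39 CPM, below the minimum level.

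Lists of immune genes had medians below 0 in PRURD2 diaphragm. Macrophage marker genes summed to 28.5 CPM in the PRURDBA and 20.1 CPM in the PRURD2 fibroblast-like cells of this tissue. The interferon response list had a median of -0.43 with 28 of 30 members below 0, and 1 member, Ifitm1, was lower by the size rule (33.4 and 14.5 CPM). Ifi47 (12.01 and 3.57 CPM), Rsad2 (11.7 and 4.02 CPM), Oas1a (5.39 and 1.51 CPM) and Usp18 (10.2 and 4.41 CPM) were more than 2-fold lower but below 20 CPM. The chemokine list had a median of -0.28, with 6 of 30 lower and 1, Ccl11, higher by the size rule. Among the lower were Cxcl9 (4.05-fold) and Cxcl14 (1543 and 480 CPM). The list member Saa3, an acute phase gene at 53.5 and 1.31 CPM, was over 5 times higher in another cell class of the tissue and stayed outside the gene counts. The complement list had a median of -0.13, with Cfb (2.68-fold) and C4b (2.23-fold) lower, and the MHC class I list of -0.11 with no member 2-fold apart. The protease list had a median of -0.14 with Mmp3, the matrix metalloproteinase stromelysin, at 526 and 147 CPM and Ctsk, the collagen-cleaving cathepsin K, at 197 and 93.1 CPM, but this median turned to 0.016 with cells thinned to 2000 UMIs and to 0.0024 at a minimum of 50 CPM. The medians of the cell cycle list (-0.16, 9 members), the glycolysis and hypoxia list (-0.06) and the TGF-beta list (-0.04) lay just below their random lists. Of these, glycolysis turned to 0.015 at a minimum of 50 CPM and TGF-beta to 0.010 with clusters weighed alike. Tgfb1 itself did not differ (33.1 and 33.1 CPM; 0.946 to 1.06). The unfolded protein response list was slightly higher (median 0.15). No list of matrix glycoproteins (0.07), collagen processing (-0.01), adipogenesis (0.15), senescence (-0.02), immediate early genes (-0.04), trophic factors (0.15), Wnt pathway (0.06), oxidative phosphorylation (0.06) or FAP identity (0.08) stood apart. Within the last of these, Thy1 (49.1 and 130 CPM) and Tek (23.5 and 63.5 CPM) were higher and the adhesion gene Vcam1 (59.8 and 18.5 CPM) lower in PRURD2. Within the matrix glycoprotein list, Tnxb and Pcolce2 were 2.20-fold and 2.14-fold higher, and within the Wnt list Sfrp1 and Dkk2 were 2.66-fold and 2.58-fold lower. Fn1, which encodes fibronectin, was at 692 and 745 CPM, a log2 ratio of 0.11 that turned to -0.26 when clusters weighed the same in both genotypes. Under the same weights 65.8% of the diaphragm calls remained, and Fmod (-0.79), Ctsk (-0.91), Dkk2 (-0.92), Pcolce2 (0.82) and Tnxb (0.99) were no longer 2-fold apart.

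In heart the question was the same for cardiac FAPs. Here 7 of 5965 genes passed the size rule, 2 higher and 5 lower in PRURD2, and the median log2 ratio of all genes was 0.06. Pax1 (ENSMUSG00000037034, chromosome 2 from 147361925 to 147393295) was 147-fold lower (21.1 and 0.144 CPM; 95% interval 82.0 to 295), from 1725 UMIs in PRURDBA and 11 in PRURD2. Cxcl13 (ENSMUSG00000023078, chromosome 5 from 95956951 to 95961068), a chemokine that attracts B cells, was 21.9-fold lower (26.5 and 1.21 CPM; 17.8 to 27.2). Of the genes always given, Postn stood in heart at 645 and 569 CPM, Col1a1 at 696 and 643 CPM, Col3a1 at 1663 and 1596 CPM, Fn1 at 138 and 134 CPM, and Acta2 at 17.5 and 14.2 CPM.

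The remaining lower genes of heart were Col6a5, a collagen VI chain, by 3.38-fold (23.03 and 6.82 CPM), Plac8 by 2.97-fold (59.96 and 20.2 CPM) and Cxcl5 by 2.04-fold (31.5 and 15.4 CPM). The higher genes were Hist1h1e, a linker histone gene, by 2.46-fold (25.8 and 63.5 CPM; 2.34 to 2.59) and Gsta3, a glutathione transferase gene, by 2.08-fold (114 and 236 CPM; 2.03 to 2.13). Cxcl5 lay at the threshold, with a log2 ratio of -0.85 over all filtered cells and -0.98 with clusters weighed alike. Gsta3 fell just below it with TMM scaling.

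List medians in heart were small. The chemokine list was lowest (median -0.19), and of its 29 members Cxcl5 and Cxcl13 were lower by the size rule. Below 20 CPM, Ccl19 (12.6 and 5.99 CPM) and Il11 (6.98 and 3.07 CPM) were more than 2-fold lower and Cxcl9 (3.08 and 8.76 CPM) more than 2-fold higher. The matricellular (-0.07), senescence (-0.07), protease (-0.07), interferon (-0.06), skeletogenic (-0.05), MHC class I (-0.04) and trophic factor (-0.0098) lists were below their random lists, with no member past the size rule. The trophic factor median turned above 0 under 4 alternatives, up to 0.076 at a minimum of 50 CPM. The interferon gene Ifi44 was 2.11-fold lower at 5.18 and 2.46 CPM. Their members included Timp1 (317 and 184 CPM), Runx1 (54.4 and 30.9 CPM), Igfbp3 (83.0 and 52.8 CPM) and Ptn, which encodes the growth factor pleiotrophin (302 and 172 CPM). The unfolded protein response list was highest (median 0.20, 18 of 20 above 0), with the chaperone gene Sdf2l1 at 55.4 and 75.4 CPM. The basement membrane list (0.12) and the matrix glycoprotein list (0.08) were above their random lists, with Lamb1 at 242 and 309 CPM. The lists of collagens (-0.03), contractile genes (-0.0034), collagen processing (0.02), TGF-beta (0.01), adipogenesis (0.06), complement (0.0013), cell cycle (0.02), immediate early genes (-0.06), Wnt pathway (0.01), oxidative phosphorylation (-0.03), glycolysis (0.02) and FAP identity (0.05) did not stand apart. Among their members the complement gene C7 was 1.69-fold higher (229 and 386 CPM) and Tgfb1 1.21-fold lower (50.3 and 41.5 CPM).

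In tibialis anterior, a limb muscle, some genes of activated fibroblasts were lower in PRURD2. The matricellular and activated fibroblast list as a whole had a median log2 ratio of -0.20 with 8 of 20 members above 0, and the median turned to 0.03 with cells thinned to 2000 UMIs. Postn (ENSMUSG00000027750, chromosome 3 from 54361109 to 54391037) was 11.4-fold lower (168 and 14.7 CPM; 95% interval 10.8 to 12.1). Mmp3 was 4.89-fold (216 and 44.2 CPM; 4.74 to 5.05), the fibulin gene Fbln7 4.45-fold and the microfibril gene Mfap4 3.99-fold lower. With clusters weighed alike the log2 ratio of Fbln7 moved from -2.15 to -1.38, and Mfap4 also moved towards 0. Higher in PRURD2 were the Ly6 family genes Slurp1, by 3.81-fold (6.32 and 24.1 CPM; 3.50 to 4.16), and Lypd2, by 3.66-fold (16.5 and 60.3 CPM), and Uchl1, a deubiquitinase gene, by 3.23-fold (22.2 and 71.7 CPM). Of 5541 genes compared, 29 were at least 2-fold higher and 26 at least 2-fold lower, while the median log2 ratio of all genes was 0.05.

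The further lower genes of tibialis anterior were Cthrc1, a secreted marker of activated fibroblasts (3.27-fold), Timp1 (84.6 and 26.1 CPM, 3.25-fold), the cell cycle inhibitor gene Cdkn2c (3.23-fold), Cilp (330 and 107 CPM, 3.08-fold) and Gxylt2 (3.00-fold). Ccdc152 was 4.06-fold lower (27.5 and 6.76 CPM), and it also led the low-depth cluster that was mostly of PRURDBA cells. The further higher genes were Col4a4 (2.90-fold), Pgf (30.1 and 81.7 CPM, 2.71-fold), Aldh1a3, which makes retinoic acid (2.56-fold), Prkg2 (2.498-fold), Sh3gl2 (2.45-fold), the secreted Wnt modulator Sfrp2 (2.38-fold) and Krtdap (176 and 410 CPM, 2.33-fold). With clusters weighed alike 45.5% of the tibialis anterior calls remained. Aldh1a3 (log2 ratio 0.79), Prkg2 (0.67), Sh3gl2 (0.96), Sfrp2 (0.92), Krtdap (0.545), Wnt2 (0.53), Vcam1 (-0.60) and Col8a1 were then less than 2-fold apart.

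Collagens were lower as a group in tibialis anterior, with 16 of 17 members below 0 and a median of -0.47. Col8a1 (190 and 77.8 CPM) was lower by the size rule, and Col6a5 was 2.55-fold lower below 20 CPM (7.86 and 3.08 CPM). Col3a1 was at 4875 and 2718 CPM, Col1a1 at 1365 and 951 CPM and Col6a3 at 489 and 262 CPM. The skeletogenic list (-0.37, 2 of 13 lower by the size rule), the protease list (-0.34, 3 of 18) and the matricellular list (-0.20, 6 of 20) were lower, with Thbs4 at 339 and 116 CPM and Ctsk at 308 and 126 CPM. Fn1 was at 2627 and 1998 CPM, Tgfb1 at 26.3 and 19.97 CPM, and Acta2 at 1.70 and 0.672 CPM. The basement membrane list had a median of -0.17 while its member Col4a4 was 2.90-fold higher. It turned to 0.08 with clusters weighed alike. Medians below the random lists were also found for collagen processing (-0.09), chemokines (-0.08), complement (-0.07) and matrix glycoproteins (-0.03), the last with Lum at 1375 and 742 CPM and Bgn at 945 and 497 CPM. The median of the last turned above 0 under 4 alternatives, up to 0.078 with clusters weighed alike. The MHC class I list was the highest, with 14 of 15 members above 0 and a median of 0.35, H2-K1 being at 481 and 670 CPM. Genes of this family are similar in sequence, so the split of counts between its single members is uncertain. The Wnt list followed (median 0.33, Wnt2 and Sfrp2 of 20 members higher by the size rule). It was 0.11 and inside its random lists with clusters weighed alike, where the interferon list, at 0.14 before, had a median of 0.03 and was inside them too. The medians of trophic factors (0.17), adipogenesis (0.16) and the unfolded protein response (0.15) were above their random lists, with Bmp2 at 66.3 and 130 CPM and the adipogenic factor gene Cebpd at 1014 and 1403 CPM. The senescence list (0.12), with Igfbp5 at 1689 and 3082 CPM, and the TGF-beta (0.11), contractile (-0.02), cell cycle (-0.09), immediate early (0.03), oxidative phosphorylation (0.04), glycolysis (0.03) and FAP identity (0.09) lists did not stand apart. In the last of these the progenitor markers Pi16 (980 and 1456 CPM) and Dpp4 (187 and 285 CPM) were less than 2-fold higher in PRURD2.

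**Figure D1:**
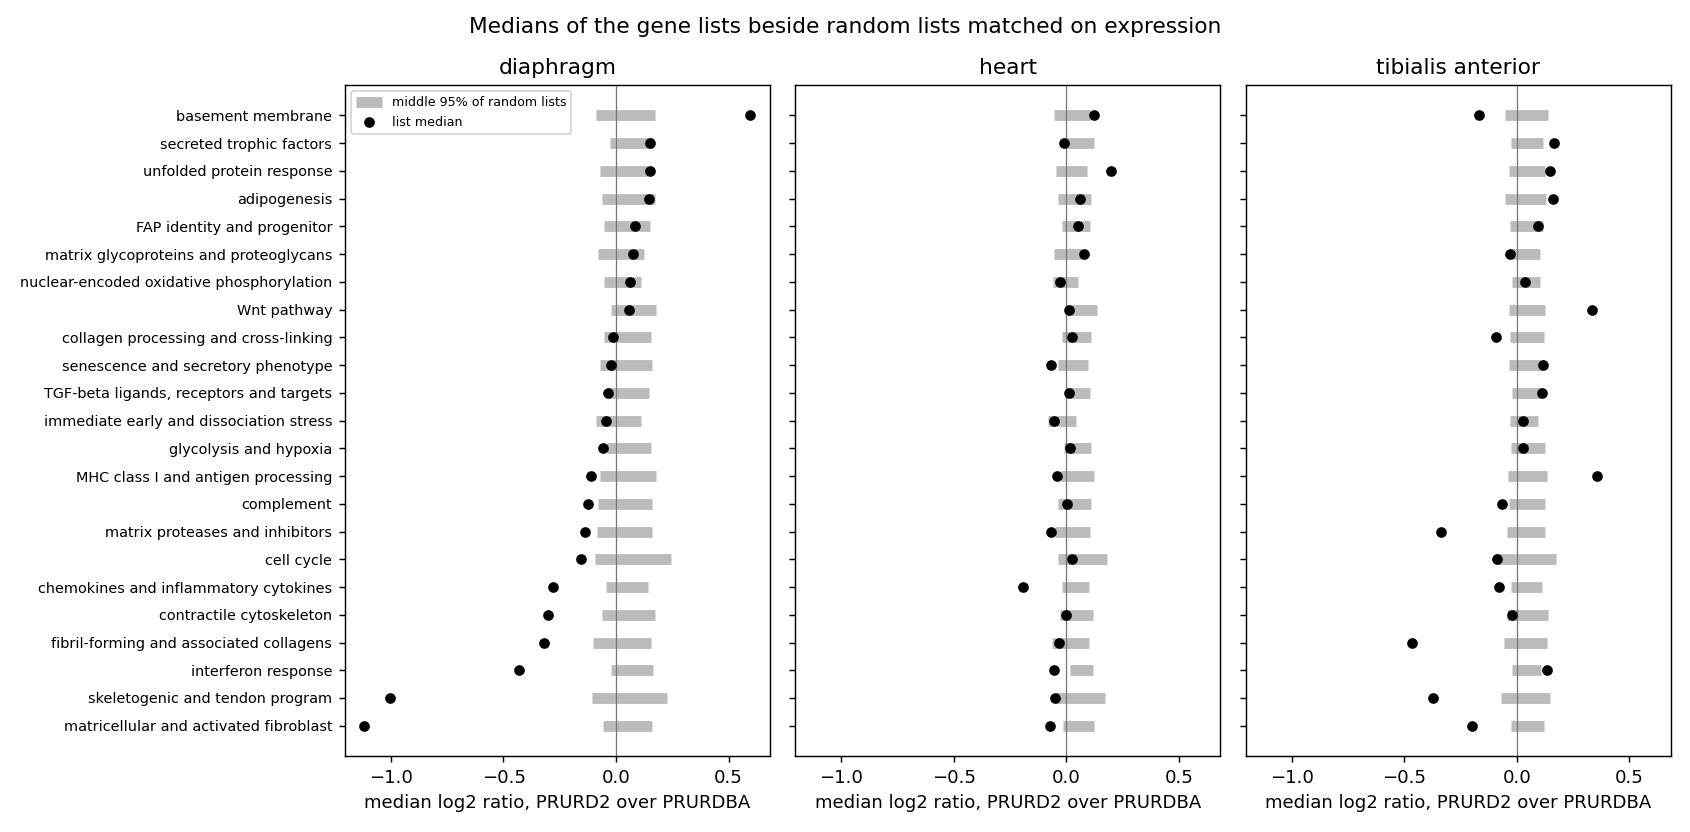
Median log2 ratio of CPM, PRURD2 over PRURDBA, of each gene list in diaphragm, heart and tibialis anterior (points), with the middle 95% of matched random lists (bars). The matricellular list lies at -1.12 in diaphragm, -0.07 in heart and -0.20 in tibialis anterior, and the basement membrane list at 0.60, 0.12 and -0.17.

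A further question was which genotype differences the tissues share. In both skeletal muscles 14 genes were at least 2-fold lower in PRURD2, among them the activated fibroblast genes Postn, Cilp, Thbs4 and Runx1 and the matrix turnover genes Timp1, Mmp3 and Ctsk. The others were Fbln7, Vcam1, Clec11a, Pdgfrl, Palld, Plscr2 and Nrep. Independent lists of the same sizes (37 and 22 genes among 5276) would share 0.154 genes. With clusters weighed alike, 11 of the 14 in diaphragm and 9 of the 14 in tibialis anterior were still at least 2-fold lower. Ctsk, Pdgfrl and Cilp dropped out in diaphragm, and Vcam1, Clec11a, Pdgfrl, Plscr2 and Nrep in tibialis anterior. Only Fbln7, Postn, Palld, Mmp3, Thbs4, Runx1 and Timp1 were then still 2-fold lower in both muscles. Higher in both muscles were Col4a4, Uchl1 and Pgf, 3 genes where independent lists would share 0.133. Diaphragm and heart shared 4 lower genes, Pax1, Cxcl5, Plac8 and Col6a5, against 0.0348 for independent lists, and no higher gene. Heart and tibialis anterior shared no called gene in either direction. No gene was called in the same direction in all 3 tissues, where independent lists would share 1.19e-05 higher and 1.95e-05 lower genes among 5078.

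Across genes, the log2 ratios of diaphragm and heart had a Pearson correlation of 0.490 and a Spearman correlation of 0.441. These values were 0.464 and 0.358 for diaphragm and tibialis anterior, and 0.306 and 0.346 for heart and tibialis anterior. Genes are not independent replicates, and whether the tissues came from the same mice is not stated. In heart, the 14 genes shared by the muscles had log2 ratios from -1.81 (Fbln7) to 0.01 (Vcam1), with Timp1 at -0.78, Runx1 at -0.82 and Postn at -0.18. Within clusters, Timp1 was lower in PRURD2 in 10 of 10 fibroblast-like clusters of diaphragm, 7 of 7 of heart and 9 of 9 of tibialis anterior. Its interval lay below 1 in 9, 7 and 7 of these. Postn was lower in 9 of 10, 5 of 7 and 8 of 9 clusters, with an interval below 1 in 9, 5 and 7. Other shared genes were less even. Thbs4 was higher, with an interval above 1, in 2 of 10 diaphragm and 1 of 9 tibialis anterior clusters, Mmp3 in 1 of 10 diaphragm and 2 of 7 heart clusters, Runx1 in 1 of 9 tibialis anterior clusters and Postn in 1 of 7 heart clusters, where it was 0.398 times as high in PRURD2 in the largest cluster and 1.09 times in the activated one. Whether the genotype difference itself differs between tissues was not tested.

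**Figure D2:**
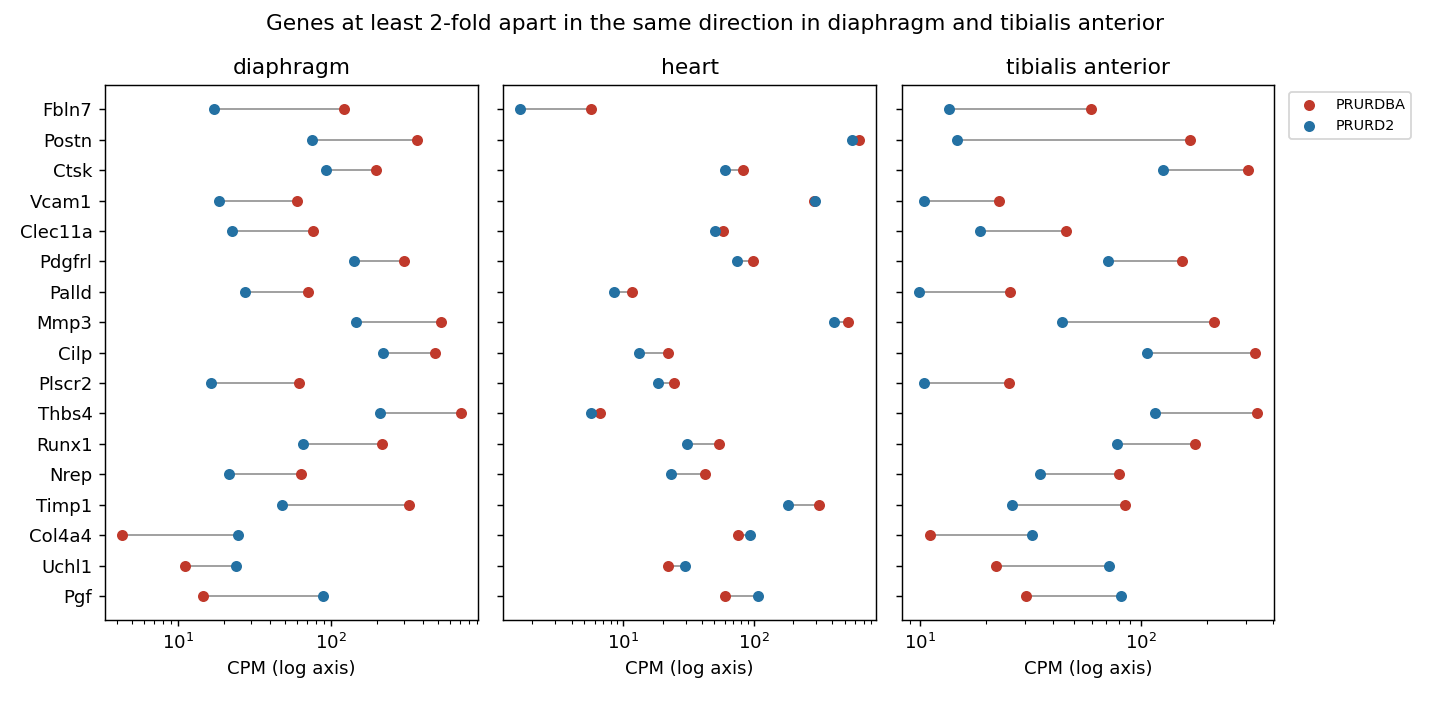
CPM in fibroblast-like cells (log axis) of the 14 genes at least 2-fold lower and the 3 genes at least 2-fold higher in PRURD2 in both skeletal muscles, with 1 point per genotype library in diaphragm, heart and tibialis anterior. Postn stands at 366 and 75.5 CPM in diaphragm, 645 and 569 CPM in heart, and 168 and 14.7 CPM in tibialis anterior.

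The last question was how FAPs of the tissues differ whatever the genotype. Heart differed from both muscles in 83 genes that were at least 2-fold higher and 87 that were at least 2-fold lower in both genotypes. Tbx20, a transcription factor of the heart field, was at 235 and 267 CPM in PRURDBA and PRURD2 heart, 0.590 and 0.711 CPM in diaphragm, and had no UMI in tibialis anterior. Tcf21, a transcription factor of epicardium-derived fibroblasts, was at 215 and 186 CPM in heart, 3.00 and 9.27 CPM in diaphragm, and had no UMI in tibialis anterior. Rhox5, a homeobox gene, was at 25.1 and 32.3 CPM in heart, had 4 and 0 UMIs in diaphragm and none in tibialis anterior. Pcdh9 was 67.0-fold, Rgs17 18.4-fold, Smim41 13.9-fold, Cst6 11.9-fold, the Wnt inhibitor gene Wif1 10.1-fold, Fblim1 8.91-fold and Fetub 8.15-fold higher in heart, as the smallest of the ratios.

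Lower in heart than in both muscles were Thbs4 (20.4-fold as the smallest ratio), Bmp5, a bone morphogenetic protein gene (17.0-fold), Krtdap (12.5-fold), Tmeff2 (12.1-fold) and Zfhx4 (11.01-fold). So were Ccn3 (10.7-fold), Myoc (9.04-fold), Sfrp4 (8.17-fold) and Cilp (8.08-fold). Over the lists, the skeletogenic and tendon program was lowest in heart, with median log2 ratios of -1.74 and -1.66 against diaphragm and -3.30 and -3.18 against tibialis anterior in PRURDBA and PRURD2. Its members went both ways, and by the size rule 1 of 12 was higher and 3 lower in heart than in diaphragm in PRURDBA, and 4 of 11 higher and 3 lower in PRURD2. Collagens were lower in heart as well (-0.87 and -0.51 against diaphragm, -0.97 and -0.40 against tibialis anterior). Contractile genes (0.24 and 0.47, 0.63 and 0.62) and MHC class I genes (0.30 and 0.33, 0.76 and 0.44) were higher.

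Diaphragm and tibialis anterior differed in 60 genes higher and 66 lower in diaphragm in both genotypes, led by genes that set position along the body axis. Hoxb2 was at 29.997 and 30.4 CPM in diaphragm and at 0.0648 and 0.356 CPM in tibialis anterior. Hoxc10 had 2628 and 2488 UMIs in tibialis anterior and 3 and 1 in diaphragm. Hoxa10 was 381-fold, the limb transcription factor genes Tbx15 and Shox2 44.9-fold and 17.4-fold, and Hoxc9 24.8-fold lower in diaphragm, as the smaller of the ratios. Tmem26 (21.98-fold), Gpr1 (11.9-fold), Procr (11.6-fold), Anxa8 (6.55-fold) and Ccdc3 (5.67-fold) were also lower. Higher in diaphragm were Col6a5 (23.2-fold), Meis2 (8.68-fold), Epha3 (5.81-fold), Sult1e1 (4.65-fold), Mfap4 (4.61-fold), Necab1 (4.39-fold), Rtl3 (4.23-fold) and Zfpm2 (4.06-fold). The Wnt list was higher in diaphragm (median 0.99 in PRURDBA and 0.33 in PRURD2), although by the size rule 6 of 23 members were higher and 2 lower in PRURDBA but 1 higher and 3 lower in PRURD2. Higher was also the unfolded protein response list (0.28 and 0.43), and the skeletogenic list was lower (-0.28 and -1.08).

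**Figure D3:**
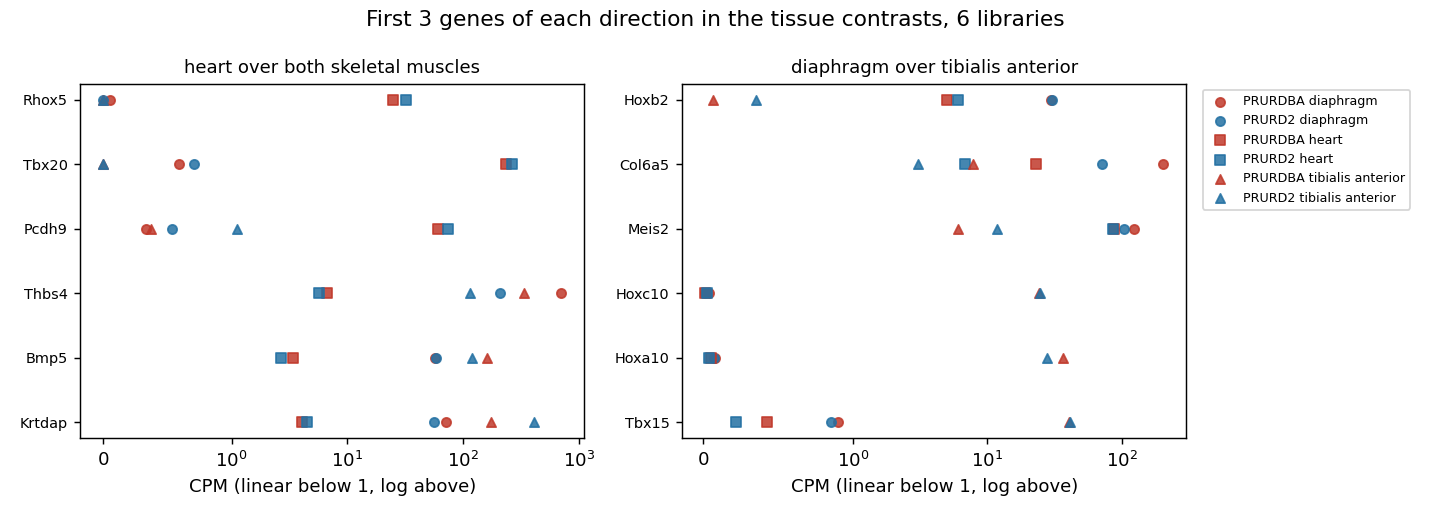
CPM in fibroblast-like cells (axis linear near 0 and logarithmic above) of the 3 genes with the largest ratios in each direction of the tissue contrasts, with 1 point per library and the genotypes of each tissue side by side. Tbx20 stands at 235 and 267 CPM in heart and at or below 0.711 CPM in the other 4 libraries.

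Fibroblast subsets were compared between genotypes only where the leading genes of a cluster did not differ 2-fold between them. In heart the Pi16/Dpp4 progenitor-like cluster held 18.2% of PRURDBA cells (95% interval 17.3 to 19.1) and 20.4% of PRURD2 cells (19.4 to 21.5). At clustering resolution 0.8 these shares were 11.8% and 13.1%. The name rested on the markers Efhd1, Sema3c, Ackr3 and Cd55, while Pi16 and Dpp4 were not among the leading genes of this cluster. Cd248, Ly6c1 and Tmem100, of the Lyve1/Ly6c progenitor-like list, were also among them, and Dpp4 was a leading gene of another heart cluster. The activated matrix-producing-like cluster of heart, led by Comp, Postn and Ltbp2, held 9.85% (9.14 to 10.6) and 9.76% (9.02 to 10.5), a difference within these intervals. In tibialis anterior a cluster led by Dmkn, Krtdap and Sbsn held 18.2% (17.6 to 18.8) of PRURDBA and 34.3% (33.3 to 35.2) of PRURD2 cells, or 21.5% and 34.7% of fibroblast-like cells. At resolution 0.8 a cluster led by the same genes held 7.76% and 16.7% of all cells. A cluster led by Stmn4, Fgf1 and Cd55 held 13.2% (12.7 to 13.8) and 15.8% (15.1 to 16.6) of all cells but 15.6% and 16.04% of fibroblast-like cells, so that its difference lay mostly in the low-depth cells of PRURDBA in the total. Clusters named Pi16/Dpp4 progenitor-like and inflammatory-like in diaphragm, interferon-responsive-like in each tissue, tenogenic-like in both muscles and Cxcl14/Smoc2 interstitial-like in tibialis anterior had leading genes that differed between genotypes, so their shares are not compared. In the main clustering no cluster was named cycling, nerve-associated, Wif1/Dkk3 cardiac or Lyve1/Ly6c progenitor-like. At resolution 0.8 a heart cluster of 167 PRURDBA and 163 PRURD2 cells was named cycling-like.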

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

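No test in this part was chosen after its result was seen, but how far an interval had to clear a bound was settled only after the values were known.

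Pi15, which encodes a peptidase inhibitor, was higher in PRURD2 in diaphragm (16.7 and 42.7 CPM, log2 ratio 1.35) and lower in tibialis anterior (27.9 and 12.1 CPM, log2 ratio -1.20). Dmkn, the dermokine gene, went the opposite way, lower in diaphragm (97.2 and 44.4 CPM, log2 ratio -1.13) and higher in tibialis anterior (235 and 512 CPM, log2 ratio 1.13). Both came up because the genotype difference had opposite signs in the muscles, and the difference between tissues was not tested. Pi15 was among the leading genes of an unnamed diaphragm cluster outside the fibroblast-like sums, whose cells did not enter its ratio. That unnamed cluster held 2.15% of PRURDBA and 0.399% of PRURD2 cells, and 5 of its 10 leading genes differed 2-fold between genotypes. Dmkn was the first leading gene of a tibialis anterior cluster that held 21.5% of PRURDBA and 34.7% of PRURD2 fibroblast-like cells. The leading genes of that cluster did not differ 2-fold between genotypes inside it. The rise of Dmkn in tibialis anterior was not separated from this change in cluster share. In diaphragm, where Dmkn was lower, a cluster led by Krtdap and Dmkn held 15.1% of PRURDBA and 25.3% of PRURD2 fibroblast-like cells. As 3 of its leading genes differed 2-fold between genotypes, these diaphragm shares are not compared.

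A diaphragm cluster outside the fibroblast-like sums came up as cells that the main comparison did not use. It held 4.46% of PRURDBA and 0.918% of PRURD2 cells and was led by Cxcl13 and Nkain4, with the MHC class II genes H2-Ab1 and H2-Aa and their partner Cd74 among its leading genes.

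A tibialis anterior cluster of low depth came up in the same way, with 15.2% of PRURDBA cells (2362 cells, median 1486.5 UMIs) and 0.880% of PRURD2 cells (83 cells, median 2258 UMIs). It was led by Ccdc152, Ulk4 and AY036118, with Gm42418, Lars2 and Timp1 also among its leading genes. Of its 10 leading genes, 6 differed 2-fold between genotypes. If these barcodes held free RNA alone, the UMIs of Dmkn, Krtdap and Sbsn, which mark 1 subset, would spread over them like random draws. Their variance was 2.33 times the binomial one (interval 2.05 to 2.67), which argues against free RNA in all of these barcodes, while it lay below the 5.75 of fibroblast-like cells thinned to 1486 UMIs, so that free RNA in part of them stays open. Damaged cells would be rich in mitochondrial UMIs, but the median share was 2.88% against 2.09% in fibroblast-like cells, a ratio of 1.38 (1.34 to 1.41), which argues against damage of that kind as the whole cause, though barcodes above 10% had already been filtered. A difference between the genotypes or the lanes stays open and was not tested, since each genotype is 1 lane in this tissue.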

How the results depend on the processing

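No test in this part was chosen after its result was seen. No test of the genotype was made. Within a tissue each genotype is 1 pooled library, which leaves no replicates to pair, and an analysis paired by tissue across the 3 tissues was not run. Of the counts of genes under the alternatives, 96 stayed within 1.5 times the reported count and 24 moved further. Of the list medians, 485 either stood apart with the same sign as before or lay inside their random lists both times, whatever their sign. A further 34 came inside their random lists and 14 went outside, with the same sign. The other 19 turned, which counts changes of sign only where a list stood apart in the main run or the alternative. Of the log2 ratios of named genes, 1597 stayed inside their counting intervals and 615 moved outside, which at this depth are narrow. The cause of the differences below was not tested, except that the minimum level sets how many genes are compared. The minima and the leaving out of genes do not touch the ratio of a named gene, and a minimum of 5 CPM equals that of list members. Some shares have no value where another clustering named no such subset.

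At a minimum of 5 CPM, 128 genes were higher and 163 lower in diaphragm, 8 and 20 in heart, and 54 and 73 in tibialis anterior, 3 were lower in all 3 tissues, 131 were higher and 152 lower in heart than in both muscles, and 138 higher and 128 lower in diaphragm than in tibialis anterior. At a minimum of 50 CPM these counts were 40 and 34 in diaphragm, 1 lower in heart, 13 and 15 in tibialis anterior, 48 and 50 for heart over the muscles, and 34 and 37 for diaphragm over tibialis anterior. List medians that turned were those of proteases (0.0024), Wnt (-0.39) and glycolysis (0.015) in diaphragm, trophic factors in heart (0.076) and matrix glycoproteins in tibialis anterior (0.0012). With no gene left out, 132 genes were higher in heart than in both muscles. With TMM scaling 1 gene was higher in heart.

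With clusters weighed alike, 16 genes were higher in tibialis anterior and 1, Plac8, was lower in all 3 tissues (log2 ratios -1.99, -1.44 and -1.01), picked out after its values were seen. The medians of TGF-beta in diaphragm (0.010) and heart (-0.039), trophic factors in heart (0.053), and basement membrane (0.084) and matrix glycoproteins (0.078) in tibialis anterior turned. With cells thinned to 2000 UMIs, those of proteases in diaphragm (0.016), trophic factors (0.019) and Wnt (-0.031) in heart, and matrix glycoproteins (0.044) and the matricellular list (0.031) in tibialis anterior turned. So did Wnt in diaphragm with doublets kept (-0.105) and over all filtered cells (-0.18), matrix glycoproteins in tibialis anterior with each cell weighted equally (0.064) and trophic factors in heart under the stricter cell filter (0.0021). These medians are small, apart from the Wnt list, whose members go both ways. The matricellular list of tibialis anterior stood at -0.20 before, and 8 of its 20 members were above 0.

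With doublets kept, the fibroblast-like share was 96.5% in PRURD2 and 92.9% in PRURDBA diaphragm and 81.3% in PRURDBA tibialis anterior. Without integration it was 97.6% in PRURD2 and 93.2% in PRURDBA diaphragm, 96.0% in PRURDBA heart and 99.3% in PRURD2 tibialis anterior. In PRURDBA heart the Pi16/Dpp4 progenitor-like share was then 16.0% and the activated share 11.4%. At resolution 0.8 the fibroblast-like share of heart was 82.3% in PRURD2 and 84.7% in PRURDBA, since a cluster with 10.3% of cells in each genotype was led by genes of another class and left out. The Pi16/Dpp4 share was then 13.1% in PRURD2 and 11.8% in PRURDBA heart, and the activated share 7.70% and 8.28%. The tibialis anterior cluster led by Dmkn, Krtdap and Sbsn held 16.7% and 7.76% at that resolution. Under the stricter cell filter the fibroblast-like share was 96.9% in PRURD2 and 91.3% in PRURDBA diaphragm, 97.4% and 96.7% in heart, and 99.4% and 95.5% in tibialis anterior, and the Pi16/Dpp4 share 21.7% in PRURD2 heart. The Pi16/Dpp4 share thus moved with the clustering by more than it differed between genotypes in heart. The Pdgfra shares of cells moved with the depth of reading, being 77.4% and 80.6% in diaphragm, 82.1% and 86.7% in heart, and 70.9% and 74.4% in tibialis anterior without thinning.

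An earlier run of the same steps used other routines of the linear algebra library, which round differently, and it moved cells between clusters. A tibialis anterior cluster was named Pi16/Dpp4 progenitor-like in that run and had no subset name here, and single list medians near the edge of their random lists changed sides. The genes shared by the muscles were the same in both runs. The first run was set aside because its routines depend on the processor, not because of its values.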

Other observations

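The tests of depth, cluster makeup and exchanged labels below were chosen only after the result was seen, as was the reading of intervals near a bound, and the test of genes near Pax1 was chosen before.

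Marker genes of other cell types were low in the fibroblast-like sums, beside 35747 to 46075 CPM for the fibroblast list. In PRURDBA and PRURD2 the endothelial markers summed to 17.2 and 21.9 CPM in diaphragm, 22.3 and 21.9 CPM in heart, and 7.39 and 8.08 CPM in tibialis anterior. Macrophage markers, led by Pf4 in heart, summed to 53.2 and 56.4 CPM in heart and 10.4 and 15.9 CPM in tibialis anterior. Mural markers stood at 175 and 206, 223 and 206, and 148 and 144 CPM in the order of tissues, and myofibre markers, for the most part Tpm3, at 255 and 214, 189 and 193, and 188 and 203 CPM. Satellite cell markers, led by Sdc4, which FAPs also express, were at 163 and 145, 138 and 164, and 134 and 158 CPM.

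Mast cell and neutrophil markers, led by Mcpt4 in heart, summed to 14.6 and 17.0 CPM in heart and at most 1.76 CPM elsewhere. Cardiomyocyte markers reached 37.8 and 32.3 CPM in heart, Schwann markers 50.5 and 55.8 CPM in heart, and lymphocyte markers 18.2 and 13.8 CPM. Mesothelial markers stood at 34.4 and 35.1 CPM in diaphragm, where a mesothelial-like cluster held 0.137% and 0.958% of cells. Adipocyte markers stood at 0.526 and 0.841 CPM in diaphragm, and erythroid markers at 0.361 and 0.504 CPM in tibialis anterior. A small diaphragm cluster led by Angptl7 and Apod held 0.231% of PRURDBA and 1.10% of PRURD2 cells.

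The 14 genes lower in PRURD2 in both muscles had a median log2 ratio of -1.74 in diaphragm and -1.33 in tibialis anterior. Depth per cell may enter such a difference. With every cell thinned to 2000 UMIs the medians were -1.65 (interval -2.15 to -1.15, 14 of 14 genes still 2-fold lower) and -1.22 (-1.81 to -0.98, 11 of 14). Thinning gives deep and shallow cells the same weight but leaves the expected share of each gene in a cell unchanged. The pattern thus did not rest on the weight of deeper cells alone, while other effects of depth cannot be decided this way. The intervals here run over the 14 genes, which were picked from the same data, and are no independent check. Weighing clusters alike took away more, to -1.43 (-2.06 to -0.94, 11 of 14) in diaphragm and -1.09 (-1.48 to -0.77, 9 of 14) in tibialis anterior. The shares of these clusters could thus account for a part of the pattern but not for the rest. Shifts of cell state inside a cluster stay in the ratios, so that makeup at a finer level cannot be excluded. Exchanged labels cannot be told apart from a genotype difference, since the labels name no carrier of the mutation and the largest Dmd ratio was 1.45. A hypothesis left open is that FAPs of the muscles are less activated in PRURD2, although the activated fibroblast list of tibialis anterior turned to 0.03 when thinned. The hypothesis was not tested, as each genotype has 1 pooled library in each muscle.

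Pax1 was lower in PRURD2 in diaphragm, heart and tibialis anterior, in the last at 3.86 and 0.0494 CPM, below the minimum level. In heart, a difference in the shares of the clusters is argued against, since the log2 ratio was -7.20 before and -7.18 after clusters weighed alike. In diaphragm it moved from -3.05 to -2.45, so that cluster shares could account for a part there. The tibialis anterior value went from -6.29 to -6.39. Shifts inside a cluster stay in these ratios. A stretch of chromosome 2 that lowers all its genes would lower the neighbours, but the 12 genes within 2 Mb had a median log2 ratio of 0.053 in diaphragm (interval -0.57 to 0.19). The 1 neighbour at least 2-fold lower was AI646519, antisense to Pax1 and overlapping its start from 147357454 to 147362793. A difference at Pax1 itself between the genotypes may account for it and was not tested.

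At a minimum of 5 CPM, Fbln7 (log2 ratios -2.83, -1.81 and -2.15 in diaphragm, heart and tibialis anterior), Cxcl5 (-2.62, -1.03 and -1.79) and Col6a5 (-1.51, -1.76 and -1.35) were at least 2-fold lower in PRURD2 in all 3 tissues. These genes were picked out after their values were seen.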
